A study of Mus musculus with 12 samples.

How the data were processed

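The series measured small RNA in extracellular vesicles from the plasma of male C57BL/6J mice, a common inbred laboratory strain, 8 days after bile duct ligation (BDL) or a sham operation. Bile duct ligation ties off the common bile duct, which stops bile flow and injures the liver. The series title speaks of mRNA and a tissue label names liver, while the site label and the protocol name vesicles from plasma and small RNA libraries, and the deposited table lists mature microRNA names. Per the labels' protocols, vesicles were precipitated from plasma with a polymer reagent (ExoQuick), small RNA libraries were built with a NEBNext kit from 40 ng of RNA with 15 PCR cycles, and 12 libraries were pooled. No molecular identifiers are described, so counts are of reads after PCR and intervals would cover counting error only.

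The deposited table holds whole-number counts per microRNA name for 12 libraries, and the authors applied no normalisation that its values show. Per the submitters' processing notes the tools were cutadapt and STAR; their versions, the genome build and the microRNA annotation are not given in the sources used here. The table has 1915 mouse names and 67 names of other species (63 with the prefix rco and 4 with hiv1), and every column of values matched 1 sample title. Only mouse names entered library sizes and tests. The labels give 6 BDL and 6 sham samples and do not state that each is a separate animal. Each first digit of the sample codes is shared by 2 libraries of the same group, 3 digits per group, and what the digit stands for is not given. The tests treat the 6 libraries of a group as separate samples, so p-values measure the spread between them; if the digit marks a shared animal or cage, these p-values may be too small, and an exact test on 1 mean per digit could not go below 0.1.

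Total counts per library ran from 121003 to 3506914. A count of 0 allows up to 3 counts, which is 24 CPM (a count scaled to a library size of 1e6) in the shallowest library (BDL 4) and 0.625 CPM in the deepest (BDL 1). Counts were tested with edgeR 4.0.16 in R 4.3.3, using its quasi-likelihood F test with trimmed-mean (TMM) scaling, its filter on low counts by group, and Benjamini-Hochberg adjustment over the 341 names that passed the filter. Adjusted p under 0.05 counted as past the threshold. The biological coefficient of variation was 45.5%. Log2 fold changes are BDL minus sham, and the standard error (SE) is the fold change divided by the square root of F. CPM values use TMM-scaled library sizes, and log2 CPM values per library have a prior count of 2. Single measures per library were compared with two-sided exact permutation tests over the 924 ways to part 12 libraries into 6 and 6, whose smallest p is 0.00216.

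The test, its samples and 23 gene lists were fixed in advance. Those lists were written for an mRNA table, and 1 of them (liver-enriched microRNAs) has members among the names tested. The other 22 could not be tested here. A further 14 microRNA lists, for cell types and microRNA families, were written after the table and the first fit had been seen, so their choice is not independent of the data. Some names stand in several lists, such as miR-25-3p and miR-92a-3p in the erythroid and miR-17/92 lists. Lists of at least 5 tested names, 1 fixed and 11 added, were tested with camera (limma 3.58.1, preset correlation of 0.01), with adjustment within the fixed and the added lists separately. Named microRNAs were the 10 largest rises and 10 largest falls past the threshold, the 2 smallest p-values and 2 highest levels in the fixed list, and the 5 highest shares of counts. Names from the added lists, miR-21a-5p, miR-194-5p, miR-215-5p, both arms of 3 hairpins and a few others, 52 in all, were chosen after the data were seen.

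Hairpin positions come from GENCODE M21 on GRCm38, which need not be the build the authors used, and 1878 of the 1915 mouse names matched a hairpin by name. GC percent was taken over the 5p or 3p side of the hairpin, since mature sequences were not used here. For names without a 5p or 3p ending, such as miR-3960 and miR-451a, it was taken over the whole hairpin. Hairpin arms, or whole hairpins for names without such an ending, were also searched for 18-base stretches in transcripts of other genes. A name with such stretches in at least 10 genes is called a sharing name. Names whose counts are identical or nearly so in every library (miR-486a-5p and miR-486b-5p, miR-199a-3p and miR-199b-3p, let-7a-1-3p and let-7c-2-3p, the 3p arms of miR-486a and miR-486b, and miR-101a-3p and miR-101c) cannot be told apart and are uncertain as separate measurements; totals count them more than once.

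Before the data were examined, the following other settings were chosen: DESeq2 size factors, total counts only, no count filter, at least 10 counts in at least 6 libraries, DESeq2 1.42.0, limma-voom, the sample number as a replicate block, the last 2 digits of the sample code (24 or 26, of unstated meaning) as a covariate, its first digit as a random block, and leaving out each library. Added after seeing the data were scaling without miR-486 and miR-451a, identical rows collapsed, each code suffix alone, thinning to the smallest library, a correction of each library for its GC trend, that correction with the replicate block, and a fit without sharing names. The steps were tested on simulated counts for the BDL against sham comparison, with 200 names changed. Of 16 names simulated at 2-fold among 333 tested, 12.5% were called, against 100% of 11 names at 4-fold and 100% of 15 at 8-fold, and 3.45% of calls were unchanged names. With no change simulated, 0 of 377 names were called. A simulated GC trend with a Spearman rho of 0.884 across 331 names fell to 0.0872 after the correction. In this single simulation changes of 2-fold were therefore mostly missed, on 16 names. In the real data some names near 2-fold were past the threshold, such as miR-24-3p (log2 fold change of 1.06) and let-7i-5p (-1.06). Others, such as miR-361-5p (1.07), were not, so the simulation sets no limit that holds for every name. Figures were drawn with matplotlib.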

Results

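The table gives microRNA counts for extracellular vesicles in plasma, the small membrane-bound particles that cells release, from 6 BDL and 6 sham libraries taken 8 days after surgery. Totals were 3506914, 623117, 2278626, 121003, 1635616 and 666310 counts in BDL libraries 1 to 6, and 2684636, 2388515, 1380297, 1407980, 1957974 and 659302 in sham libraries 1 to 6. The mean was 1.47 ± 1.27 (in units of 1e6 counts) in BDL and 1.75 ± 0.744 in sham (SD, n = 6 each; exact permutation p = 0.667). BDL libraries with code suffix 26 were shallow, at 0.121 to 0.666 in the same unit, against 1.64 to 3.51 for BDL suffix 24, 1.38 to 2.68 for sham suffix 24 and 0.659 to 2.39 for sham suffix 26. At least 1 count was found for 892.7 ± 280.4 names in BDL and 937.5 ± 154.5 in sham (SD, n = 6 each; exact permutation p = 0.76).

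The comparison asks which vesicle microRNAs differ in plasma after the bile duct is tied. Of 341 names tested, 84 were higher and 62 lower in BDL (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p under 0.05). The liver microRNA miR-122-5p rose 19.2-fold, while miR-451a, which is abundant in red blood cells, fell by 2.63 on the log2 scale. Names past the threshold numbered 74 higher and 52 lower of 403 tested in the 6 libraries with suffix 24, and 54 higher and 48 lower of 265 in the 6 with suffix 26. Of the 146 names past the threshold in all 12 libraries, 98 were past it in the same direction in suffix 24 and 88 in suffix 26, where fewer names could be tested, with 0 in the opposite direction in either. These libraries also gave the 146 names, so this agreement is partly built in. miR-6372 (-2.01 in suffix 24 and 1.87 in suffix 26) and miR-8117 (-2.02 and 1.17) passed the threshold in opposite directions. They are not among the 146. The first principal component, 53.1% of the variance, placed every BDL library below every sham library, with BDL 2, 4 and 6 farthest out.

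**Figure D1:**
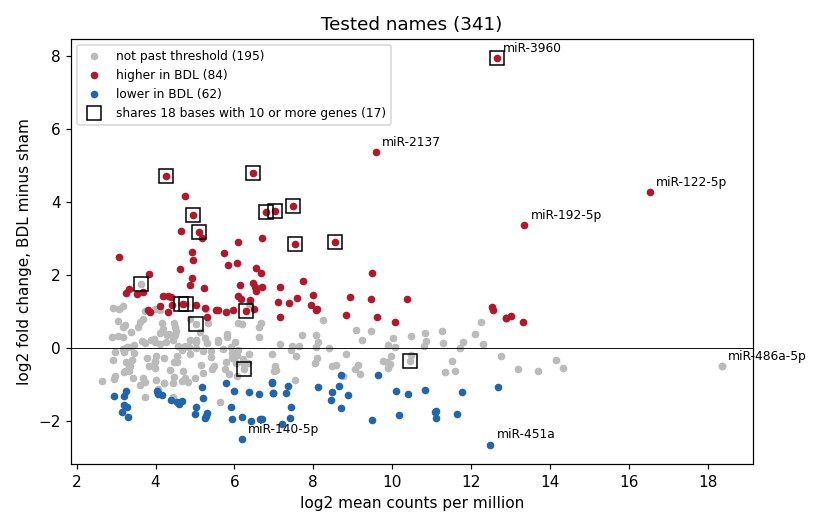
Log2 fold change (BDL minus sham) against log2 mean CPM for the 341 tested names, 1 point each; red points (84) were higher and blue points (62) lower in BDL, and squares mark the 17 sharing names. miR-122-5p is the most abundant name past the threshold, and the sharing names past it all lie above 0.

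Liver-enriched microRNAs took a larger share of the BDL libraries, a rise that was mostly miR-122-5p, the most abundant microRNA of hepatocytes. miR-122-5p (hairpin Mir122, chromosome 18, 65248861 to 65248926 on the plus strand, in an exon of the lincRNA AC157910.3) reached 180067 ± 86734 CPM in BDL against 9368 ± 8113 in sham (SD, n = 6 each), a log2 fold change of 4.26 ± 0.55 (SE; adjusted p = 3.81e-05), and every BDL library exceeded every sham library. miR-192-5p, a microRNA of liver and gut (Mir192, chromosome 19, 6264844 to 6264932, outside other genes), rose from 1847 ± 508.7 to 19062 ± 10313 CPM, a log2 fold change of 3.37 ± 0.34 (adjusted p = 3.13e-06). miR-193a-5p (Mir193a, chromosome 11, 79711969 to 79712034) rose by 3.21 ± 0.39 (adjusted p = 2.48e-05). miR-148a-3p, the abundant liver member, had a log2 fold change of -0.32 ± 0.29 (adjusted p = 0.406).

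The list did not move 1 way. Of its 23 tested members, 6 were higher, 6 lower and 11 not past the threshold, and adjusted over the list alone the counts were also 6 and 6. Its median log2 fold change was -0.14 and its mean 0.30, so these differ in sign, and camera gave p = 0.682, upward (p = 0.853 with an estimated correlation); its direction was downward without BDL 1 (p = 0.69) and in suffix 26 (p = 0.48). fry tests the list's own names against no change, not against other names. Its directional p was 0.424, and its mixed p, for change in either direction, was 2.25e-13. Every list tested had a fry mixed p of 0.00256 or less, so the mixed p does not set this list apart. By share of counts the list took 23.5 ± 10.7% in BDL and 3.8 ± 1.35% in sham (SD, n = 6 each; exact permutation p = 0.00216, the smallest possible). miR-122-5p alone was 18.7 ± 9.31% of BDL and 0.926 ± 0.824% of sham counts (n = 6 each, exact permutation p = 0.00216). The list's share differed by 19.7 percentage points and that of miR-122-5p by 17.8, so the rise in share was mostly this name. Within suffix 24 the log2 fold change of miR-122-5p was 5.07 ± 0.51 and within suffix 26 it was 3.94 ± 0.59 (n = 3 per group; adjusted p = 4.91e-05 and 2.34e-04 by edgeR). For miR-192-5p these were 4.01 ± 0.42 and 2.60 ± 0.36.

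**Figure D2:**
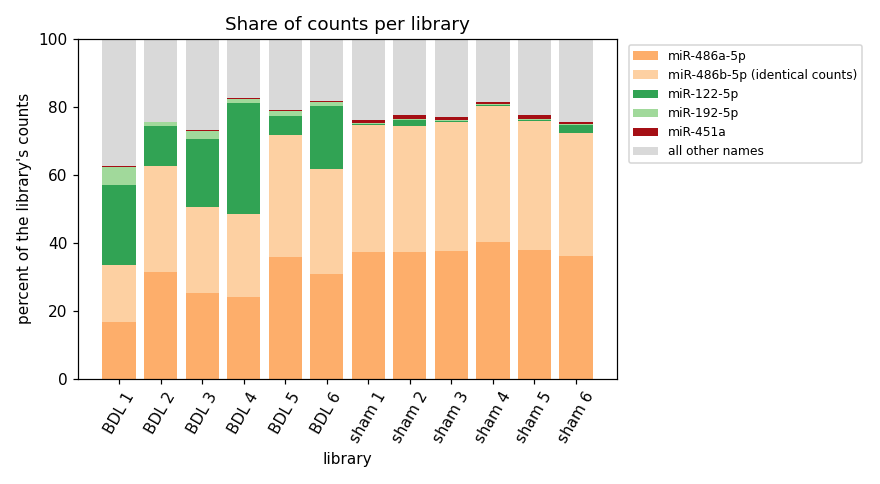
Percent of each library's counts, stacked from 0, for the most abundant name and its identical copy, miR-122-5p, miR-192-5p and miR-451a. miR-122-5p takes 5.77 to 32.7% of each BDL library and 0.29 to 2.28% of each sham library.

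Among hepatocyte names, a list written after the data were seen, miR-122-5p and miR-192-5p rose while miR-194-5p had a log2 fold change of 0.78 ± 0.40 (adjusted p = 0.124; 0.93 without BDL 4, adjusted p = 0.0309). Within suffix 24 miR-194-5p rose by 1.36 ± 0.33 (adjusted p = 0.00939) and within suffix 26 it had -0.10 ± 0.51 (adjusted p = 0.876); the difference between suffixes had an adjusted p of 0.252. miR-215-5p, a close relative of miR-192, fell by 1.18 ± 0.30 (adjusted p = 0.00451; -0.66 and 0.135 in suffix 24). The list, too short for camera with 3 tested names, took 20.9 ± 9.87% of BDL counts against 1.13 ± 0.871% in sham (n = 6 each, exact permutation p = 0.00216, adjusted 0.0101 over 14 lists). Most of this share was miR-122-5p.

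Several erythroid microRNAs were lower in BDL, in a list also written after the data were seen. Of 11 tested names 0 were higher, 5 lower and 6 not past the threshold (camera adjusted p = 0.00184, or 0.485 with an estimated correlation). The 5 lower names include miR-486a-3p and miR-486b-3p, whose counts are nearly identical. miR-451a (Mir451a, chromosome 11, 78073170 to 78073241) had 1595 ± 706.9 CPM in BDL and 9909 ± 2108 in sham (SD, n = 6 each), a log2 fold change of -2.63 ± 0.33 (adjusted p = 3.51e-05), with every BDL library below every sham library. Its log2 fold change was -2.20 ± 0.29 in suffix 24 and -3.24 ± 0.47 in suffix 26. miR-16-5p fell by 2.06 ± 0.46 and miR-486a-3p by 1.74 ± 0.24. miR-486a-5p (Mir486, chromosome 8, 23142555 to 23142682, in an intron of Ank1, a red cell membrane protein) was the most abundant name, and its log2 fold change was -0.49 ± 0.28 (adjusted p = 0.162). miR-25-3p and miR-92a-3p had -0.63 ± 0.35 and -0.56 ± 0.24 (adjusted p = 0.16 and 0.0679). For miR-25-3p the value was -0.0095 ± 0.29 in suffix 24 (adjusted p = 0.977) and -1.67 ± 0.38 in suffix 26 (adjusted p = 0.00358), and the difference between suffixes had an adjusted p of 0.0618. Without BDL 1, miR-25-3p had -0.92 (adjusted p = 0.0462), and without BDL 5 or sham 6 miR-92a-3p had -0.79 or -0.76 (adjusted p = 0.0183 and 0.0232). The list took 57 ± 13.1% of BDL counts and 79.9 ± 2.66% of sham counts (n = 6 each; exact permutation p = 0.00216, adjusted 0.0101). Most of this is miR-486a-5p and its identical copy miR-486b-5p; without these 2 the list took 2.32 ± 1.22% and 4.32 ± 0.7% (n = 6 each; exact permutation p = 0.00866). The log2 ratio of miR-451a to miR-23a-3p, used as a sign of haemolysis in plasma, was 0.000227 ± 1.48 in BDL and 3.77 ± 0.552 in sham (n = 6 each; exact permutation p = 0.00216). miR-23a-3p itself had a log2 fold change of 1.35 ± 0.45 (adjusted p = 0.0215), with 2.02 ± 0.43 in suffix 24 and 0.40 ± 0.52 in suffix 26 (adjusted p = 0.559). It was not past the threshold without BDL 1 (0.78, adjusted p = 0.111) or without sham 3, 5 or 6 (1.14, 1.22 and 1.17, adjusted p = 0.0716, 0.0723 and 0.0719), nor with the replicate block (1.12, adjusted p = 0.0646).

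**Figure D3:**
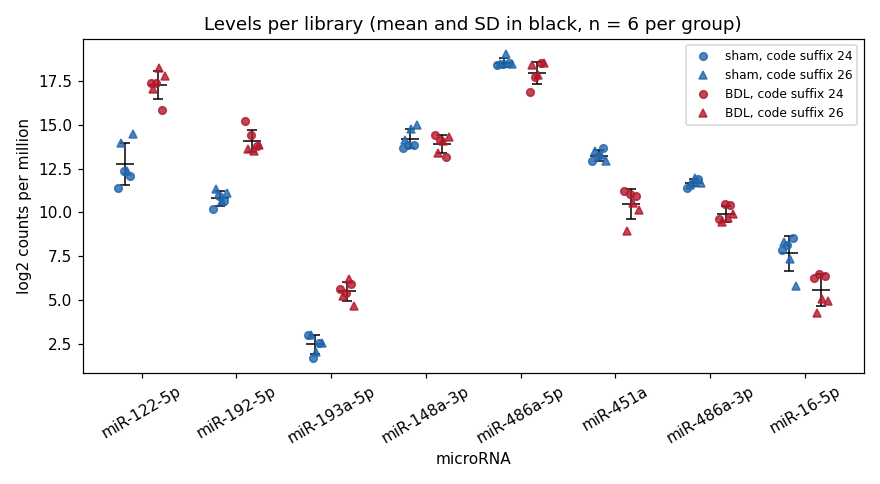
Log2 CPM per library for 8 microRNAs, sham in blue and BDL in red, circles for code suffix 24 and triangles for 26, with the mean and SD (n = 6 per group) in black. The groups do not overlap for miR-122-5p, miR-192-5p, miR-193a-5p, miR-451a and miR-486a-3p, and overlap for miR-148a-3p, miR-486a-5p and miR-16-5p.

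The largest rises were mostly in names that share sequence with many transcripts. miR-3960 (Mir3960, chromosome 2, 32712900 to 32712972, in an exon of Cdk9) had a log2 fold change of 7.93 ± 1.07 (adjusted p = 5.54e-05), from 53.22 ± 21.23 CPM in sham to 12926 ± 23888 in BDL, where BDL 2 had 61290 CPM; without BDL 2 it was 5.77. miR-2137 (chromosome X, 72992079 to 72992144, in an intron of Zfp185), which has no such stretch, rose by 5.36 ± 0.54 (4.72 without BDL 2). miR-6964-5p, given below, has no such stretch either. miR-3473a rose by 4.78 ± 0.70 (2.97 in suffix 24 and 5.40 in suffix 26) and miR-1934-3p by 3.76 ± 0.61 (2.24 and 4.22). miR-3473e (4.71 ± 0.82), miR-6964-5p (4.16 ± 0.82), miR-3470b (3.89 ± 0.58), miR-3473f (3.74 ± 0.71) and miR-3470a (3.64 ± 0.72) became 3.98, 3.25, 3.19, 2.91 and 2.61 without BDL 2, all still past the threshold; miR-6964-5p was not past it in suffix 24 (1.41, adjusted p = 0.076). In suffix 24 miR-3960, miR-3470b, miR-3473f and miR-3470a had 5.35, 2.494, 2.02 and 1.82, all past the threshold. In suffix 26 these were 8.32, 4.325, 4.16 and 4.72. Of 17 tested sharing names, 11 were higher, 0 lower and 6 not past the threshold. The median log2 fold change was 2.90 in sharing names and -0.02 in 318 other names (permutation p = 1e-05, the smallest possible, in a test across names, which are not independent replicates). Most sharing names have no 5p or 3p ending, so their whole hairpin was searched. Sharing was therefore not separated from lacking such an ending. Within suffix 24 the difference of medians was 1.56 and within suffix 26 it was 3.70.

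The largest falls were smaller than the largest rises and were in names known from several tissues. After miR-451a, the largest were miR-140-5p, known from cartilage (-2.47 ± 0.45, adjusted p = 4.07e-04), and miR-16-5p. miR-455-5p had -2.0 ± 0.52 (adjusted p = 0.00566; -3.13 without BDL 1; -1.10 and 0.137 in suffix 24). miR-150-5p, of mature lymphocytes, had -1.96 ± 0.42, and miR-181d-5p -1.94 ± 0.43. miR-205-5p, of stratified epithelium, had -1.94 ± 0.29 and miR-206-3p, of skeletal muscle, -1.94 ± 0.42. miR-26b-5p had -1.92 ± 0.45 and miR-148b-3p -1.91 ± 0.33. All 10 had adjusted p at or below that of miR-455-5p.

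Other lists written after the data were seen gave mixed counts. Of 13 leukocyte names 1 was higher, 4 lower and 8 not past the threshold (camera adjusted p = 0.0779), with miR-142a-5p at -1.90 ± 0.36, miR-146b-5p at -1.62 ± 0.34 and miR-146a-5p at 0.09 ± 0.35 (adjusted p = 0.87). Of 10 platelet and endothelial names 2 were higher, 3 lower (5 when adjusted over the list alone) and 5 not past it (camera adjusted p = 0.287), with the endothelial miR-126a-3p at -1.79 ± 0.40 (-0.69 and adjusted p = 0.0549 in suffix 24) and miR-24-3p at 1.06 ± 0.25 (adjusted p = 0.103 in suffix 26 and 0.0617 with no count filter). Of 4 striated muscle names 3 were lower, among them miR-499-5p (-1.87 ± 0.40) and miR-1a-3p (-1.20 ± 0.39; adjusted p = 0.394 in suffix 26, 0.106 thinned, 0.115 with GC correction and 0.0661 with that and the replicate block), and miR-133a-3p had -0.34 ± 0.47 (adjusted p = 0.602). The pancreatic islet miR-375-3p, the 1 tested name of its list, had -0.73 ± 0.22 (adjusted p = 0.0148; 0.0986 with total counts only, 0.189 with no count filter, 0.112 in suffix 24 and 0.0675 in suffix 26). Of 5 epithelial names 1 was higher and 2 lower (camera adjusted p = 0.287), with miR-200b-5p at 1.63 ± 0.47 (adjusted p = 0.0111; 0.0593 without sham 3, 0.0609 with no count filter and 0.0523 with GC correction and replicate block) and miR-200a-3p at -0.14 ± 0.36 (adjusted p = 0.792).

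Names tied to fibroblasts and stellate cells, the matrix-forming cells of injured liver, also split. Of 12 tested, 3 were higher, 3 lower and 6 not past the threshold (camera adjusted p = 0.609). The 3 lower names include miR-199a-3p and miR-199b-3p, whose counts are identical. miR-214-3p had 1.69 ± 0.29 (adjusted p = 3.37e-04) and miR-143-3p -1.13 ± 0.25 (adjusted p = 0.00189). miR-21a-5p, often raised in fibrotic tissue, had 0.00 ± 0.30 (adjusted p = 1). Of 6 neural names 3 were higher and 2 lower (camera adjusted p = 0.609), with miR-129-5p at 1.79 ± 0.32 and miR-128-3p at -1.20 ± 0.23. By share of counts the neural list fell from 0.49 ± 0.0929% in sham to 0.257 ± 0.0636% in BDL (n = 6 each; exact permutation p = 0.00216, adjusted 0.0101), which is the fall of miR-128-3p: without it the share rose from 0.0163 ± 0.00283% to 0.0361 ± 0.0149% (n = 6 each; exact permutation p = 0.00433).

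Of 15 let-7 names, 2 of them (not past the threshold) with identical counts, 1 was higher, 3 lower and 11 not past the threshold (camera adjusted p = 0.0779), with let-7c-5p at -1.24 ± 0.25, let-7i-5p at -1.06 ± 0.24 and let-7b-5p at -0.35 ± 0.20 (adjusted p = 0.162). In the miR-17/92 and paralogous clusters, which act in cell growth, 0 of 14 were higher and 6 lower (camera adjusted p = 0.0473; adjusted p = 0.485 with an estimated correlation), with miR-20a-5p at -1.81 ± 0.48 and miR-17-5p at -1.77 ± 0.47. In the miR-26, miR-27 and miR-101 families 0 of 8 were higher and 6 lower (camera adjusted p = 0.0473, or 0.485 with an estimated correlation), with miR-26a-5p at -1.83 ± 0.36 and miR-27a-3p at 0.19 ± 0.33 (adjusted p = 0.682). The 6 lower names of these families include miR-101a-3p and miR-101c, whose counts are nearly identical. Without BDL 2, 4 or 6 or sham 5 the camera call of both lists ended (adjusted p = 0.0706, 0.0817, 0.0582 and 0.06), and without sham 2 that of the second (0.051). Of 9 miR-30 names 1 was higher and 2 lower (camera adjusted p = 0.297), with miR-30e-5p at -1.64 ± 0.42, miR-30a-3p at -1.04 ± 0.26 (adjusted p = 0.0714 in suffix 24 and 0.0739 with no count filter), miR-30d-5p at 0.87 ± 0.26 (adjusted p = 0.0694 without sham 3, 0.21 in suffix 26 and 0.143 with no count filter) and miR-30a-5p at 0.47 ± 0.40 (adjusted p = 0.387; -0.25 without BDL 1). Of 17 names of the chromosome 12 imprinted cluster 5 were higher (4 when adjusted over the list alone) and 1 lower (camera adjusted p = 0.287), with miR-136-5p at 2.41 ± 0.43, miR-134-5p at 1.84 ± 0.35 and miR-409-3p at 1.26 ± 0.38 (adjusted p = 0.104 in suffix 26 and 0.0518 with no count filter).

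The names with the highest shares of counts besides miR-122-5p were miR-486a-5p and miR-486b-5p, with identical counts, miR-99a-5p and miR-148a-3p. miR-486a-5p fell from 37.8 ± 1.3% of sham counts to 27.3 ± 6.74% of BDL counts (n = 6 each; exact permutation p = 0.00216), while its scaled log2 fold change was not past the threshold. miR-99a-5p had a log2 fold change of -0.55 ± 0.28 (adjusted p = 0.127). Fold changes rose with GC percent across 335 names with a hairpin (Spearman rho = 0.316; permutation p = 1e-05, across names): in the GC-richest of 3 equal parts 46 names were higher and 7 lower, and in the GC-poorest 16 were higher and 31 lower. Within suffix 24 rho was 0.175 and within suffix 26 it was 0.308.

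**Figure D4:**
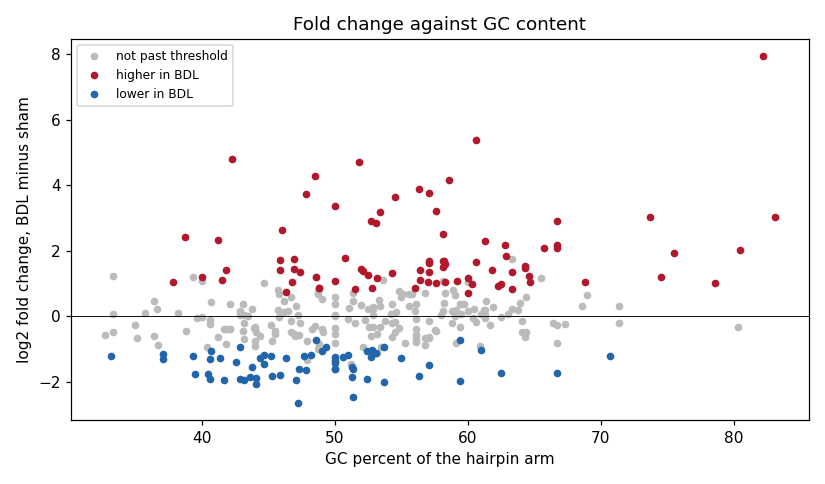
Log2 fold change (BDL minus sham) against GC percent of the hairpin arm for 335 tested names, 1 point each, red higher, blue lower and grey not past the threshold. Above 56.4% GC 46 names are higher and 7 lower in BDL.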

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

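The tests of a few abundant names, of red cell RNA as the whole cause, and of the shallow libraries for miR-122-5p and miR-451a were chosen after the results were seen, as were the GC correction, the fits within a code suffix and the correlations of sharing names with the suffix taken out. Of 190 groups of 6 values, 16 held a library far from the others, where chance gives about 1 in 20.

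In BDL 4, the shallowest library, log2 CPM was low for miR-140-5p (0.21), miR-206-3p (0.21), miR-434-5p (0.21), miR-99a-5p (12.70), miR-133a-3p (5.62) and miR-434-3p (3.20); a value of 0.21 there is a count of 0, which allows up to 24 CPM. In sham 6 log2 CPM was low for miR-21a-5p (10.63), miR-20a-5p (3.74), miR-17-5p (4.76) and miR-92a-3p (12.86) and high for let-7b-5p (12.03), miR-409-3p (7.70) and miR-709 (4.39). In sham 4 miR-486a-5p and miR-486b-5p were high (19.05 for both). The miR-30 family took 3.83% of counts in BDL 1, above the other BDL libraries.

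The effect of BDL differed between code suffixes 24 and 26 for 8 names (edgeR interaction test; 67 at an unadjusted p under 0.05). Of these, 4 kept their direction: miR-126a-3p (interaction -2.53 on the log2 scale; -0.69 in suffix 24 and -3.28 in suffix 26), miR-6964-5p (3.82; 1.41 and 5.10), miR-200c-3p (-2.84; -1.08 and -4.01) and miR-3473b (2.80; 1.04 and 3.75). The other 4 turned: miR-6372 (3.92; -2.01 and 1.87), miR-8117 (3.22; -2.02 and 1.17), miR-8114 (2.31; -1.25 and 0.98) and miR-30c-5p (-2.16; 0.33 and -1.93). Of the 4 that turned, miR-8114 was not past the threshold in suffix 26 (edgeR adjusted p = 0.0692). Nor was miR-30c-5p in suffix 24 (edgeR adjusted p = 0.499). All 8 names but miR-6964-5p were named after their values were seen. Names of other species, outside the comparisons, had 41 ± 23.5 counts per 1e6 counts in BDL and 20.9 ± 7.84 in sham (SD, n = 6 each; exact permutation p = 0.0801).

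The 146 names past the threshold in the real grouping were matched by 1 of 100 splits drawn from 462, the real one itself. The highest of the other splits gave 19. If the 12 libraries are separate samples, this argues against chance alone as the source of the count. If the first digit of the code marks a shared animal or cage, the splits cannot decide this, since they move single libraries.

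Of 17 sharing names 11 were higher in BDL and 6 not past the threshold. After the GC correction the difference of medians was 3.01 (permutation p = 1e-05, the smallest possible) and within suffix 24, without the 3 shallowest BDL libraries, it was 1.56 (permutation p = 2.00e-05), which argues against a GC trend or shallow libraries as the whole cause. Within groups the sharing names varied together, with a mean pairwise correlation of 0.539 across libraries, above the 0.158 that 95% of 10000 matched random sets stayed under (0.478 and 0.179 without BDL 2). With the code suffix taken out as well the correlation was 0.18, against 0.153 for random sets (0.232 and 0.119 with log2 depth also out), and without BDL 2 it was 0.137, against 0.142, so much of it follows the suffix. Whether fragments of other transcripts were counted under these names cannot be told from these values, and a biological rise of such fragments in BDL plasma is untested.

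miR-122-5p and miR-192-5p were higher in BDL. Scaled by total counts only, miR-122-5p had a log2 fold change of 4.34 while the other tested names had a median of 0.124 (SD 1.34 over names), so a loss of counts from abundant names, which lifts all others alike, is not the whole cause. After GC correction miR-122-5p had 4.49 ± 0.57 and within suffix 24 it had 5.07 ± 0.51, which argues against a GC trend or shallow libraries as the whole cause. Release of hepatocyte RNA after BDL may account for the rise, as a hypothesis found on the same data; miR-148a-3p, also abundant in liver, was not past the threshold, miR-194-5p was past it in suffix 24 (1.36) and not over all libraries (0.78), and vesicle yield was not measured here.

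Of 11 erythroid names 5 were lower in BDL and 6 not past the threshold, and the list's camera call was lost with an estimated correlation (adjusted p = 0.485). miR-451a had -2.41 ± 0.30 after GC correction and -2.20 ± 0.29 within suffix 24, which argues against a GC trend or shallow libraries as the whole cause. The log2 ratio of miR-451a to miR-486a-5p was lower in BDL by a difference of -2.2 (SE 0.562, BDL minus sham). A fall by the same amount in every erythroid name could therefore not be the whole cause. The log2 ratio of miR-486a-3p to miR-486a-5p, arms of the same hairpin, was also lower in BDL (difference -1.2, exact permutation p = 0.00216). Ratios thus shifted even within a hairpin, so the first ratio cannot decide how far red cell RNA fell. The log2 ratio of miR-451a to miR-23a-3p, a sign of haemolysis, was also lower in BDL (difference -3.77; exact permutation p = 0.00216). Less red cell RNA as a cause of the fall, including less haemolysis in BDL than in sham samples, and a larger share of counts going to liver names, stay open.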

How the results depend on the processing

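Alternatives with a code suffix alone, thinning, GC correction, collapsed rows, scaling without miR-486 and miR-451a or without sharing names, and all results of added lists, were chosen after seeing the data. Planned settings without haemoglobin genes were not run, since the table lists microRNA names, and the first-digit block was not run for list tests. No name past the threshold in all 12 libraries passed it in the opposite direction under any setting. The settings reuse these libraries, so this is partly built in. For 60 named microRNAs past the threshold, 1695 values under alternatives had the same direction, and 88 of these, for 19 names, were no longer past it. Many of the 60 were chosen for large changes or small p-values, so this count does not describe all names. Of all 146 names past the threshold, 145 were also past it with the first-digit block. This was 104 with GC correction and replicate block, and 87 with no count filter. The count with the first-digit block cannot show that a shared digit does no harm, for the reason given below. The median over names moved by -0.14 with DESeq2 size factors, 0.11 with total counts and -0.17 with DESeq2. Higher names numbered 84, with 54 in suffix 26 (265 names tested) and 38 thinned (134 tested); lower names numbered 62, with 33 thinned. Leaving out 1 library gave 65 to 89 higher and 54 to 70 lower.

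The sample numbers do not pair the libraries: same-numbered deviations correlated at 0.0994, -0.0886, -0.0768, -0.0615, 0.311 and 0.296, and 2 of 6 matched best with their own number. With the replicate block 72 names were higher and 61 lower. With the first digit of the code as a random block 92 were higher and 85 lower, at a correlation within digits of -0.221. The libraries that share a first digit always differ in code suffix, and this fit had no term for the suffix. Any difference between suffixes would therefore lower the correlation within digits. So neither the correlation nor the counts can show that libraries sharing a digit are unrelated.

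Of 11 added lists tested 3 passed. This became 1 with total counts only, the stricter filter, collapsed rows, suffix 24, suffix 26 (10 tested), thinning (7 tested), GC correction and without sharing names, 10 of 14 with no count filter (8 of the 11 lists tested above, besides hepatocyte and striated muscle), 0 with an estimated correlation and 5 with fry, and 1 to 5 when 1 library was left out; the erythroid list passed in each of these except with the estimated correlation. The count of 5 with fry answers another question, since fry tests a list against no change and camera tests it against the other names. The difference in names detected, -44.83, was 21.17 after thinning and -104.5 to 48.9 with 1 library left out (48.9 without BDL 4).

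The liver-enriched list, not past the threshold, turned downward without BDL 1 (camera adjusted p = 0.69) and in suffix 26 (0.48). Directions also turned in microRNAs not past the threshold and in shares; the cause was not tested. miR-148a-3p had 0.21 in suffix 24 and 0.011 with GC correction and replicate block. miR-146a-5p had -0.037 with DESeq2 size factors, -0.062 with DESeq2, -0.029 with voom, -0.13 with the replicate block, -0.047 with the first-digit block, -0.58 in suffix 26, -0.13 with GC correction and block, and -0.30 to 0.17 with 1 library left out. miR-200a-3p had 0.20 in suffix 24, 0.10 with GC correction and 0.0059 with that and the block. miR-21a-5p had -0.13 with DESeq2 size factors, -0.064 with no filter, -0.062 with the stricter filter, -0.16 with DESeq2, -0.034 with the replicate block, -0.061 with the suffix covariate, -0.11 collapsed, -0.41 in suffix 26, -0.0065 without sharing names, and -0.24 to 0.12 with 1 library left out. miR-6372 (0.36) had -0.063 with no filter, -0.24 with voom, -0.11 with the suffix covariate, -0.21 with the first-digit block, -2.01 in suffix 24, and -0.31 to 1.06 with 1 library left out. miR-8114 (0.18) had -0.14 with no filter, -0.012 with DESeq2, -0.44 with voom, -0.21 with the replicate block, -0.14 with the suffix covariate, -0.40 with the first-digit block, -1.25 in suffix 24, -0.36 with GC correction, -0.66 with that and the block, and -0.31 to 0.34 with 1 library left out. miR-8117 (-0.20) had 1.17 in suffix 26 and -0.77 to 0.39 with 1 library left out, and miR-30c-5p (-0.40) had 0.33 in suffix 24. In suffix 26 miR-30a-5p had -0.65, miR-27a-3p -0.52 and miR-194-5p -0.10. miR-27a-3p had -0.12 with GC correction and -0.31 with the block too; with 1 library left out it ran from -0.12 to 0.32 and miR-30a-5p from -0.25 to 0.59. As percent of counts without miR-486 and miR-451a, the difference was -2.86 for platelet and endothelial, -0.585 for miR-30 and -0.0207 for chromosome 12 names, against 0.0367, 0.663 and 0.0495 of all counts. The neural difference, -0.233, was 0.0198 without miR-128-3p. With 1 library left out the platelet and endothelial difference ran from -0.269 to 0.188 and the fibroblast difference (-0.0544) from -0.178 to 0.00833. A count of 0 allows the most CPM in BDL 2, 4 and 6, of suffix 26 (5.4, 24 and 5.51), followed by sham 6 (4.58).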

Other observations

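The arms of a hairpin often moved apart. Of 63 hairpins with both arms tested, the ratio of the arms differed between BDL and sham in 23 (exact permutation test, adjusted p under 0.05 over 63), 9 had both arms past the threshold in the same direction and 3 in opposite directions. These 3, named after their values were seen, were miR-143 (5p 1.51 ± 0.56, 3p -1.13 ± 0.25), miR-434 (5p -1.45 ± 0.40, 3p 1.05 ± 0.41) and miR-503 (5p -1.47 ± 0.43, 3p 0.85 ± 0.30). The higher arm of each rests on few counts or a narrow margin: leaving out 1 library ended the call of miR-143-5p in 9 of 12 cases and of miR-434-3p and miR-503-3p in 10 of 12 each. Within suffix 24 the lower arms miR-434-5p and miR-503-5p were also not past the threshold (adjusted p = 0.114 and 0.191), nor was miR-434-5p with GC correction and replicate block (0.0749). The difference of arms was 2.79, -2.64 and -2.43 (5p minus 3p, log2; exact permutation p = 0.00216 for each, adjusted 0.00718). In the liver list miR-148a-5p had 1.74 ± 0.39 (adjusted p = 0.115 in suffix 26) beside its uncalled 3p arm. A GC trend between libraries may pull arms apart. The difference in GC between hairpin sides did not track the difference in fold change across hairpins (Spearman rho = 0.101, permutation p = 0.429). This cannot decide the question, since the sides of a hairpin pair with each other and have similar GC. The 5p and 3p sides had 44.7% and 46.8% for miR-434, and 58.1% and 53.1% for miR-143.

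Across names, Spearman rho between GC percent and log2 fold change was 0.316 (permutation p = 1e-05), 0.331 without sharing names and 0.175 within suffix 24. This rho describes the trend and is no separate test of it. The correction brings rho to 0.0338 by construction; with it 72 names were higher and 61 lower, 118 of them shared with the 146 in direction. Whether the trend is technical was not settled.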
